A study of Mus musculus with 12 samples.

How the data were processed

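The deposited table holds raw read counts per gene symbol, made by the authors from single-end reads of 100 bases, with 23365 genes and 1 column for each of 12 libraries. Per the labels, RNA was depleted of ribosomal RNA and amplified with 15 PCR cycles, and the authors named TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq and edgeR 3.8.6 with the mouse build mm9. The roles of these tools, the gene annotation and the library strandedness used in counting are not stated, but each column name says that strand was ignored. Values were checked to be whole numbers, and no normalization by the authors was found. All columns were matched to samples through the labels, and 0 sample columns stayed unmatched.

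Libraries were grouped by the labels into pro-B (n = 3), YY1 knockout pro-B (KO, n = 3), pre-B (n = 2), follicular B (FOB, n = 2) and germinal centre B (GCB, n = 2). The comparisons were KO against pro-B, pre-B against pro-B, FOB against pre-B and GCB against FOB. The groups, comparisons, tests, gene lists, the rule for naming genes and most of the other settings were all set before the data were examined.

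Analyses ran in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as another tool, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with low counts were removed with the filterByExpr function by group, which left 13986 genes. Libraries were scaled by the trimmed mean of M-values (TMM). All 12 libraries were fitted together with 1 coefficient per group, so that the 2-library groups share the estimate of spread with the others. The common dispersion was 0.0862 and the prior degrees of freedom were 3.70. Each contrast was tested with the quasi-likelihood F test, which is two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No minimum fold change was set. Log2 changes are edgeR estimates with standard errors from the same test, and CPM values are counts per 1000000 of the TMM-scaled library size, given as mean and sample SD.

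For each comparison the text names Yy1, the 10 largest rises and the 10 largest falls. These were taken among genes past the threshold, with a mean log2 CPM of at least 3 over all libraries and no overlap between the groups. Unnamed models, receptor segments, histone genes, small RNA genes and pseudogenes were left out of these by patterns in their symbols, which did not cover the small RNA gene Rprl3. Genes were ranked by fitted log2 change, also where a group had no counts. Up to 4 members of each gene list, those with the smallest p, are named as well, and genes that define a sort or genotype were used as label checks. A gene with no counts in a group is given a bound, with the group set to 3 counts in all. With 1 to 3 counts, the pooled ratio is given with its exact 95% counting interval.

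The 29 gene lists covered early B-lineage, B-lineage identity, mature follicular, germinal centre and plasma cell genes. Other cell types were covered by T-lineage, natural killer, granulocyte and monocyte, erythroid, megakaryocyte, dendritic and stromal lists. The remaining lists held oxidative phosphorylation, mitochondrially encoded, mitochondrial and cytosolic ribosomal protein, cell cycle, histone, p53 target, interferon-stimulated, glycolysis, unfolded protein response, immediate early, Polycomb, Hox, cohesin with condensin and Ctcf, immunoglobulin variable segment (2 lists) and sex-linked genes. The mitochondrially encoded list and both immunoglobulin segment lists matched 0 genes of the table and gave no result, which left 26 lists. Each was tested with the camera function of limma at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison, and again with an estimated correlation. Members past the threshold were counted over all genes tested and adjusted over the list alone. List means per library used log2 of CPM plus 1. The direction of a camera test compares the members with all other genes and can differ from the sign of a median.

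On simulated counts with the same design and depths, the edgeR test recovered 93% of 4-fold and 38% of 2-fold changes for KO against pro-B, 88% and 25% for pre-B, 79% and 15% for FOB and 79% and 18% for GCB. Of its calls, 5.07%, 9.60%, 6.0% and 4.90% were false in the same order, against 17.3%, 23.4%, 22.8% and 15.8% for DESeq2. The simulation changed 100 genes by each factor, fewer than were called in the data, and did not include differences between batches. Its shares therefore need not hold for these libraries. The lowest detection floor of 3 counts was 0.0644 CPM over the pro-B libraries, and the highest was 0.273 CPM over the GCB libraries.

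The other settings tried were size factors by relative log expression, no low-count filter, DESeq2, a fit of the 2 groups compared, a term for the replicate number, a term for the numeric code in the labels, a test against a 2-fold change, removal of special gene classes, the estimated correlation, the rotation test fry, and omission of each library in turn. After seeing the data, further settings were added: pro-B library 3 alone, KO library 3 alone, the Rn45s share as a covariate, the granulocyte list mean as a covariate and a crossed replicate term. Where an omission left 1 library in a group, that library was assumed to vary like those of the other groups. Libraries of 1 group were treated as replicates per the labels, which do not say whether any are repeat preparations of 1 sample. No sample was left out.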

Results

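RNA-seq read counts were available for 12 mouse B-lineage libraries in 5 groups, all on the C57BL/6 background per the labels. Pro-B cells (n = 3) came from the bone marrow of RAG1-deficient mice, in which B-cell development stops before antigen receptors are assembled. Rag1 still read 878 ± 122 counts per 1000000 (CPM, mean ± SD, n = 3) in these libraries, and counts per gene cannot show whether that transcript is intact. YY1 knockout pro-B cells (n = 3, written KO) came from RAG-deficient mice whose floxed Yy1 alleles were deleted by mb1-Cre, a recombinase expressed from the start of the B lineage. Pre-B cells (n = 2) came from RAG-deficient mice carrying an IgM transgene. Follicular B cells (FOB, n = 2) were sorted from spleen. Germinal centre B cells (GCB, n = 2) were sorted from spleen 8 days after immunization with ovalbumin and lipopolysaccharide in alum.

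Total counts were 19253624, 13534450 and 6535564 in pro-B libraries 1, 2 and 3, and 8420609, 6052470 and 5377558 in KO libraries 1, 2 and 3. The pre-B libraries held 19811157 and 9637112 counts, the FOB libraries 3639414 and 21001613, and the GCB libraries 7720502 and 5580440. Ribosomal precursor RNA (Rn45s) took 1.26%, 1.38% and 0.646% of counts in the pro-B libraries and 18.1%, 15.6% and 0.777% in the KO libraries. Its share was 0.514% and 8.22% in pre-B, 12.5% and 27.4% in FOB, and 17.8% and 19.1% in GCB. The labels give each library a numeric code of unstated meaning. Pro-B libraries 1 and 2 and pre-B library 1 share code 87, and pro-B library 3 and KO library 3 share code 150. KO library 1 shares a code with GCB library 1, KO library 2 shares another with FOB library 1 and GCB library 2, and pre-B library 2 and FOB library 2 have codes of their own. Codes are treated here as possible batches. Pro-B libraries 1 and 2 detected 1017 and 1380 of 1456 olfactory and vomeronasal receptor genes, which are mostly silent outside sensory tissue, whereas pro-B library 3 detected 40. The other libraries detected between 33 and 223. The labels do not state that libraries came from separate animals, so adjusted p-values measure the spread between these libraries. Intervals and detection floors cover counting error only, because the reads carry no molecular identifiers. Counts were made without regard to strand, so overlapping antisense transcripts are counted together with the named gene. Positions are not given because the counting annotation is not stated.

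YY1 is a zinc-finger transcription factor, and its own transcript was measured first. Yy1 stood at 92.8 ± 7.78 CPM (mean ± SD, n = 3) in pro-B and at 26.2 ± 22.2 CPM (n = 3) in KO, a log2 change of -1.83 (SE 0.46, edgeR adjusted p = 0.0266). The 3 KO libraries differed from each other: they held 8.42, 19.1 and 51.2 CPM, or 9.07%, 20.6% and 55.1% of the pro-B mean. All 3 lay below every pro-B library. Counts per gene cannot show whether the remaining Yy1 came from pro-B cells or from other marrow cells. The call was lost without pro-B library 1 (adjusted p = 0.0821), pro-B library 2 (0.0608), pro-B library 3 (0.0512) or KO library 2 (0.111). With a term for the library code, which rests on the pair of libraries of code 150, the log2 change was -0.90 (adjusted p = 0.184). Fitting only the 6 pro-B and KO libraries gave -1.83 (adjusted p = 0.0901). Along the stages, Yy1 was at 126 ± 6.01 CPM in pre-B, 122 ± 4.14 CPM in FOB and 139 ± 5.91 CPM in GCB (each SD, n = 2). None of the stage differences passed: the log2 change was 0.44 (SE 0.49, adjusted p = 0.533) for pre-B against pro-B, -0.05 (SE 0.54, adjusted p = 0.952) for FOB against pre-B and 0.20 (SE 0.54, adjusted p = 0.838) for GCB against FOB. These values rest on a shared spread that includes the KO libraries, where Yy1 varied most. Fits of only the 2 groups compared gave 0.43 (adjusted p = 0.0797), 0.01 (0.973) and 0.24 (0.143) in the same order, so none passed there either.

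**Figure D1:**
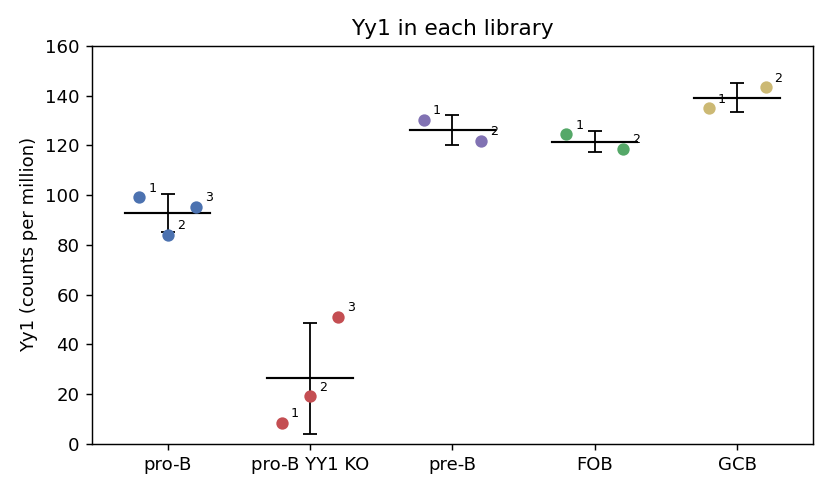
Yy1 in CPM in each of the 12 libraries, 1 point per library numbered by replicate, with the mean and SD of each group as bars. The KO libraries sit at 8.42, 19.1 and 51.2 CPM, below the lowest pro-B library at 84.1 CPM.

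The first comparison, KO against pro-B, asks what changes in pro-B cells when YY1 is deleted. Some pro-B genes were almost lost in KO. Cacna2d1, a calcium channel subunit gene, fell from 80.8 ± 6.86 to 1.26 ± 0.737 CPM, a log2 change of -6.00 (SE 0.40, adjusted p = 6.41e-05, SD and n = 3 per group). Tet1, which encodes a DNA 5-methylcytosine oxidase, fell from 63.9 ± 7.67 to 4.08 ± 2.12 CPM, a log2 change of -3.97 (SE 0.30, adjusted p = 8.07e-05). In the other direction, Ifi44l, an interferon-induced gene, rose from 0.218 ± 0.340 to 38.6 ± 16.2 CPM, a log2 change of 7.27 (SE 0.89, adjusted p = 0.00188). Genes of oxidative phosphorylation and of cytosolic ribosomes were lower as groups, and interferon-stimulated, immediate early and granulocyte and monocyte genes were higher, by the camera test with its preset correlation. None of these 5 lists passed with an estimated correlation (adjusted p from 0.734 to 0.745), and in each of them most members did not pass.

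Among the 10 largest falls were also Zfp827 (log2 -4.92), Apbb1 (-4.63), Eps8l1 (-3.83), Smtnl2 (-3.74), Nipsnap1 (-3.62), Plekha5 (-3.62), Pcp4l1 (-3.55) and Eps8l2 (-3.52), with adjusted p from 6.41e-05 to 0.00231. Besides Ifi44l, the 10 largest rises were C5ar1 (log2 3.36), the receptor of complement fragment C5a, S100a11 (3.31), Lcn2 (3.05), a neutrophil granule protein gene, Pram1 (2.95), Atn1 (2.94), Cish (2.90), a cytokine-signalling inhibitor gene, Mmp25 (2.87), Oas2 (2.86) and Ifitm1 (2.78). Their adjusted p ran from 0.000332 to 0.0208. Of these 20 genes, 16 passed whichever library was left out. Atn1 did not pass without pro-B library 1 (adjusted p = 0.0920), pro-B library 2 (0.0549), pro-B library 3 (0.0562) or KO library 2 (0.0752). Lcn2 did not pass without pro-B library 1 (0.0704) or KO library 2 (0.0538). Without pro-B library 1, S100a11 (0.0519) and Cish (0.0632) did not pass either. Within code 150, the single code with both genotypes, KO library 3 differed from pro-B library 3 in the same direction for all 20, but with KO library 3 as the single knockout library S100a11 (adjusted p = 0.0727), Atn1 (0.508) and Cish (0.280) did not pass. Lcn2 (adjusted p = 0.111), Atn1 (0.191), Cish (0.184) and Mmp25 (0.0554) did not pass with the code term.

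Of 77 nuclear-encoded oxidative phosphorylation genes, 30 fell, 0 rose and 47 did not pass (43 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.44. Examples were the respiratory chain genes Cox7a2l (-1.38, SE 0.18, adjusted p = 0.00135) and Ndufc1 (-1.33, SE 0.18, adjusted p = 0.00146) and the ATP synthase gene Atp5a1 (-1.17, SE 0.18, adjusted p = 0.00288). The list passed the camera test (adjusted p = 6.31e-10), but not with an estimated correlation between genes (adjusted p = 0.734). Of 77 cytosolic ribosomal protein genes, 21 fell, 0 rose and 56 did not pass (36 fell adjusted over the list alone), with a median of -0.44 and a camera adjusted p of 1.18e-07 (adjusted p = 0.745 with an estimated correlation). Rps13 (-0.98, SE 0.15) and Rpl22 (-0.75, SE 0.15) were among them. Ribosomal protein genes have many pseudogenes of near-identical sequence. Within code 150, 70 of 77 oxidative phosphorylation genes and 77 of 77 cytosolic ribosomal protein genes were lower in KO library 3 than in pro-B library 3, with mean differences of -0.38 and -0.52. The other libraries gave -0.49 and -0.38. Of 73 mitochondrial ribosomal protein genes, 17 fell, among them Mrpl9 (-1.07) and Mrpl27 (-0.87), 2 rose (Mrps15 and Mrps2, named after their values were seen) and 54 did not pass (21 fell and 3 rose adjusted over the list alone). Their median was -0.26 and their camera adjusted p was 0.0120 (adjusted p = 0.745 with an estimated correlation, 0.227 without KO library 3 and 0.136 without the low-count filter).

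Interferon-stimulated genes were higher in KO: 7 of 23 rose, 0 fell and 16 did not pass (14 rose adjusted over the list alone), with a median of 0.77. Oas2 (2.86, SE 0.51), Oasl2 (2.34, SE 0.40) and Ifi44 (2.32, SE 0.41), all induced in antiviral responses, passed (adjusted p from 0.00456 to 0.00582). For this list the camera adjusted p was 4.71e-06 (adjusted p = 0.734 with an estimated correlation). The list mean was higher by 0.59 within code 150 and by 0.97 among the other libraries. Immediate early genes, which respond within minutes to signals and to stress, had a median of 1.41. Of 16, 4 rose (Zfp36, Klf6, Egr1 and Ier3), 0 fell and 12 did not pass (5 rose adjusted over the list alone), with a camera adjusted p of 0.00027 (adjusted p = 0.734 with an estimated correlation). Zfp36 rose by 2.46 (SE 0.49, adjusted p = 0.00983) and passed whichever library was left out. Egr1 read 127.8, 75.9 and 3.32 CPM in KO libraries 1, 2 and 3 and 8.56, 6.10 and 1.94 CPM in the pro-B libraries. Its log2 change of 3.58 (adjusted p = 0.0292) did not pass without pro-B library 1, 2 or 3 (adjusted p = 0.0790, 0.0926 and 0.0749) or KO library 1 or 2 (0.0746 and 0.0747). Klf6 did not pass without pro-B library 2 or 3 (0.0884 and 0.0597) or KO library 2 (0.0653). Ier3 did not pass without pro-B library 1, 2 or 3 (0.148, 0.125 and 0.0501) or KO library 1 or 2 (0.0572 and 0.143). Within code 150 the mean of the immediate early list differed by 0.10, against 1.77 among the other libraries, and the list did not pass with the code term (adjusted p = 0.890) or with the Rn45s share as a covariate (adjusted p = 0.211). Among the KO libraries the Rn45s share moved with this list: it was 18.1% and 15.6% in KO libraries 1 and 2 and 0.777% in KO library 3. Of the 2-library groups, FOB went the same way (list mean 0.92 at 12.5% and 2.82 at 27.4%). Pre-B (-0.27 at 0.514% and -0.75 at 8.22%) and GCB (1.55 at 17.8% and 0.73 at 19.1%) did not.

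Granulocyte and monocyte genes had a median of 1.28 in KO. Of 24, 6 rose, 0 fell and 18 did not pass (6 rose adjusted over the list alone), with a camera adjusted p of 0.00066 (adjusted p = 0.745 with an estimated correlation, and 0.227 without KO library 3). With the mean of this list as a covariate among the 8 marrow libraries, the megakaryocyte list (adjusted p = 0.167) and the mitochondrial ribosomal protein list (0.229) did not pass either, while the erythroid (0.000306) and natural killer (0.00187) lists passed as lower. As reported, the erythroid list (median -0.94) did not pass (camera adjusted p = 0.0836, and 0.823 with an estimated correlation). It passed as lower without pro-B library 1 (0.0377), pro-B library 2 (0.00363) or KO library 3 (0.0213). It also did so with the replicate number (0.0221) or the code term (0.0373). Nor did the natural killer list pass as reported (0.0574, and 0.745 with an estimated correlation). It passed as lower without pro-B library 1 (0.0486), pro-B library 2 (0.0166) or KO library 3 (0.00368), and in a fit of the 2 groups alone (0.0254). Csf3r, the receptor for granulocyte growth factor, rose by 2.33 (SE 0.42, adjusted p = 0.00589) and Mmp9, a neutrophil protease gene, by 2.63 (SE 0.52, adjusted p = 0.00957). These transcripts were also abundant in pro-B: S100a9, an abundant neutrophil transcript, read 2477, 692 and 2609 CPM in the pro-B libraries and 1646, 5553 and 8405 CPM in the KO libraries. C5ar1, Lcn2, Pram1 and Mmp25, among the largest rises, are likewise expressed in granulocytes. Megakaryocyte and platelet genes had a median of 1.90, with 1 of 8 (Gp1ba) rising, 0 falling and 7 not passing (2 rose adjusted over the list alone). Their camera adjusted p was 0.0120 (adjusted p = 0.734 with an estimated correlation), and it was 0.0571 without pro-B library 3 and 0.201 without KO library 3. Gp1ba itself (log2 1.70, adjusted p = 0.0114) did not pass without pro-B library 1 (adjusted p = 0.0605).

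The early B-lineage list had a median of -0.61 and passed as lower (camera adjusted p = 0.00157), but not with an estimated correlation (0.734) or with fry (0.0827). Of 18 genes, 5 fell (among them Dntt, Cd93, Vpreb1 and Igll1), 1 rose (Kit) and 12 did not pass (7 fell and 2 rose adjusted over the list alone). Igll1 and Kit were named after their values were seen. Dntt, the template-independent polymerase that adds bases at receptor gene joints, fell from 2431 ± 145 to 423 ± 181 CPM, a log2 change of -2.52 (SE 0.37, adjusted p = 0.00231). Cd93, the surface antigen of immature B cells, fell by 1.48 on the log2 scale (SE 0.17, adjusted p = 0.00073). The list mean differed by -1.24 within code 150 and by -0.48 among the other libraries. KO library 3 also had the highest granulocyte and monocyte list mean of the KO libraries (2.28 relative to pro-B). Its share of B-lineage cells was not measured. Vpreb1 did not pass without pro-B library 1 (adjusted p = 0.0625), pro-B library 2 (0.0516) or KO library 2 (0.0615). Of 24 B-lineage identity genes, 6 fell, 3 rose and 15 did not pass, and the list did not pass (adjusted p = 0.454), though it passed as lower with the code term (0.00583), the Rn45s covariate (0.00227) and KO library 3 alone (0.0216). Its members moved apart: Cd22, an inhibitory B-cell receptor partner, rose by 2.78 (SE 0.23), while Blk and Cd72 fell by 1.86 and by 1.59 on the log2 scale. Of 23 mature follicular genes, 7 rose, 3 fell and 13 did not pass (list adjusted p = 0.0948). This list passed as higher without the low-count filter (0.00410), with the code term (0.00583), without KO library 2 (0.0339), with the Rn45s covariate (0.0490), and with pro-B library 3 (0.0296) or KO library 3 (0.00503) alone. Ciita, the activator of class II antigen presentation, rose by 1.58 (SE 0.15) and the chemokine receptor gene Cxcr5 fell by 2.85 on the log2 scale (SE 0.37).

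Of 18 p53 target genes, 5 rose, 1 fell and 12 did not pass (5 and 1 adjusted over the list alone), with a median of 0.55 and a camera adjusted p of 0.0120 (adjusted p = 0.734 with an estimated correlation, 0.0770 without KO library 1, 0.167 with the code term and 0.204 with the Rn45s share as a covariate). The fall was Trp53inp1 (-1.06, SE 0.17, adjusted p = 0.00338), and the rises included Pmaip1, a cell-death activator gene, and Aen and Ei24, which were named after their values were seen. Pmaip1 read 18.0 CPM in KO against 4.67 CPM in pro-B (log2 1.93, adjusted p = 0.0172), and did not pass without pro-B library 2 (adjusted p = 0.0669) or KO library 2 (0.0548). Of 60 replication-dependent histone genes, whose copies share sequence, 7 fell, 0 rose and 53 did not pass (4 fell adjusted over the list alone), with a median of -0.33. Hist1h1a (-1.04, SE 0.21) and Hist3h2ba (-0.94, SE 0.16) were among them. The histone list had a camera adjusted p of 0.0107 (adjusted p = 0.823 with an estimated correlation), and 0.247 without pro-B library 3 or 0.188 without KO library 3. Cell cycle genes did not pass as a list (adjusted p = 0.492), but passed as lower with the code term (0.00592) and with pro-B library 3 alone (0.0137), and 30 of 35 were lower within code 150, against 19 of 35 among the other libraries. Of these genes, 2 of 35 fell (among them Mcm5, -0.86, SE 0.13), 0 rose and 33 did not pass. The 16 lists that did not pass had adjusted p between 0.0574 and 0.840. The stromal list passed as higher in 5 other settings, among them the code term (0.000117) and without KO library 1 (0.0409). Its mean differed by 1.46 within code 150 and by -0.12 among the other libraries. Relative to pro-B it was -0.56, 0.24 and 1.53 in KO libraries 1, 2 and 3, so the rise was mainly that of KO library 3. In the plasma cell list the median was -0.41 and the mean 0.13 with a test direction of down, and in the dendritic cell list the median was 0.25 and the mean 0.13 with a test direction of down.

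Across all 13986 genes tested, 882 rose and 1187 fell in KO at an adjusted p under 0.05 (edgeR quasi-likelihood F test, Benjamini-Hochberg), and 486 and 593 of them changed at least 2-fold. The unadjusted p was under 0.05 for 4425 genes. In 32.8% of genes the groups did not overlap, against 10% by chance for 3 libraries against 3. The number of rises was 187 without pro-B library 1, 248 without pro-B library 2, 279 without KO library 2 and 1480 without KO library 3. The number of falls was 537 without pro-B library 1, 614 without pro-B library 2 and 485 without KO library 2. With the code term 135 genes rose and 341 fell. Without both libraries of code 150, 1446 genes rose, and 76.6% of them were also higher in KO library 3 than in pro-B library 3, against 48.2% of all genes. Of the 1466 genes that fell without these libraries, 85.8% were also lower in KO library 3, against 51.0% of all genes. The changes of these genes, which were picked outside the code, were smaller within it: as differences of log2 of CPM plus 1, the medians were 0.95 outside and 0.27 within for rises, and -1.04 and -0.59 for falls. Other settings that moved the counts by over 1.5 times were DESeq2 (1391 rises), a fit of the 2 groups alone (512 rises), a test for changes beyond 2-fold (20 rises and, rounded, 1.1e+02 falls), pro-B library 3 alone as control (9 and 64) and KO library 3 alone (597 falls). List members named above that did not pass with the code term were Ndufc1 (adjusted p = 0.0723), Atp5a1 (0.0599), Rps13 (0.0560), Mrpl27 (0.0756), Csf3r (0.0534), Mmp9 (0.0789), Blk (0.0513), Cd72 (0.203), Trp53inp1 (0.0810), Mcm5 (0.0907) and Zfp36 (0.139). With pro-B library 3 alone as control, 11 of the 20 largest changes did not pass (adjusted p from 0.0707 to 0.324). Of the other 69 named list members that passed, 32 did so whichever library was left out.

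**Figure D2:**
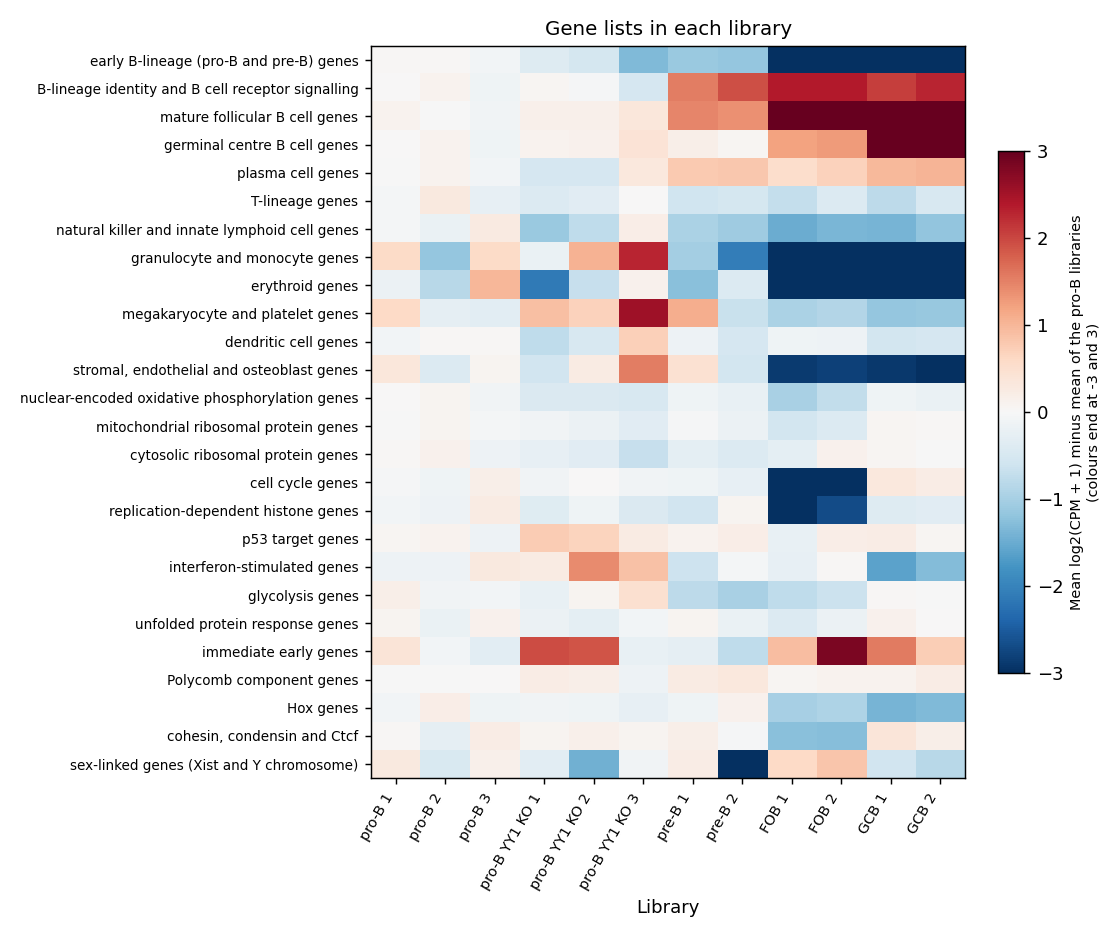
Mean expression of each gene list in each library, as log2 of CPM plus 1 averaged over the members, minus the mean of the pro-B libraries. Colours end at -3 and 3, and the immediate early list reads red in KO libraries 1 and 2 but not in KO library 3, while the early B-lineage and granulocyte lists end at the blue limit in FOB and GCB.

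The comparison of pre-B with pro-B cells follows the next stage in the marrow, after an IgM heavy chain is expressed. Dntt fell from 2431 ± 145 CPM (n = 3) to 9.97 ± 3.03 CPM (n = 2), a log2 change of -7.91 (SE 0.58, adjusted p = 1.28e-05). Ikzf3, which encodes the lymphoid transcription factor Aiolos, rose from 5.85 ± 1.16 to 344 ± 179 CPM, a log2 change of 5.86 (SE 0.40, adjusted p = 1.07e-05). Cd2, an adhesion receptor gene, rose from 1.02 ± 0.350 to 134 ± 9.37 CPM, a log2 change of 7.11 (SE 0.62, adjusted p = 3.80e-05). Genes of B-lineage identity and of mature follicular B cells rose as groups. The glycolysis and cytosolic ribosomal protein lists were lower by the camera test with its preset correlation, but not with an estimated one (adjusted p = 0.727 and 0.902), and 67 of 77 cytosolic ribosomal protein genes did not pass.

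The other large rises were Rbm24 (log2 7.57), Flrt2 (7.30), Me1 (7.22), Fcrla (6.77), Il2ra (6.69), which encodes a chain of the interleukin-2 receptor, Polm (6.47), a DNA polymerase gene, Lars2 (5.98) and Rprl3. Rprl3, a small RNA gene, had 2 counts over the pro-B libraries, a pooled ratio of 6837 with a 95% counting interval of 1892 to 56463. Lars2 moved with the Rn45s share: it read 840.5 CPM in the pre-B library with 0.514% Rn45s and 20134 CPM in the pre-B library with 8.22%. Lars2 was also the single gene among these 20 that did not pass whichever library was left out. Its adjusted p was 0.0917, 0.0750 and 0.0845 without pro-B library 1, 2 and 3, and 0.349 without pre-B library 2. It also did not pass with a term for the replicate number (0.109) or with pro-B library 3 alone as control (0.195). The other large falls were Fxyd6, Rnase12 (log2 -6.38), Arpp21 (-6.20), Myl10 (-5.69), Ttll11 (-5.54), Pcp4l1 (-5.53), Als2cl (-5.49), Scn4b (-5.24) and Mmrn1 (-5.03). Fxyd6 had 3 counts over the pre-B libraries, a pooled ratio of 294 with a counting interval of 100.4 to 1427.

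Of 24 B-lineage identity genes, 17 rose, 0 fell and 7 did not pass (19 rose adjusted over the list alone), with a median of 1.43. Blk (3.37, SE 0.23), Cd22 (3.76, SE 0.24), Spib (2.81, SE 0.18) and Ralgps2 (3.30, SE 0.19) were among them, and Blk encodes a kinase of B-cell receptor signalling. Of 23 mature follicular genes, 14 rose, 2 fell (Cxcr5 and Bcl2, named after their values were seen) and 7 did not pass (15 and 3 adjusted over the list alone), with a median of 1.76. Ciita rose by 3.70 (SE 0.16, adjusted p = 2.76e-06), and S1pr1, which guides lymphocyte exit from tissue, by 3.14 (SE 0.27, adjusted p = 3.66e-05). The camera adjusted p was 1.55e-19 for the identity list and 2.30e-11 for the follicular list. Both also passed with an estimated correlation (adjusted p = 0.0181 and 0.0094). Of 9 plasma cell genes, 3 rose (Sdc1, Irf4 and Prdm1), 0 fell and 6 did not pass, with a median of 0.24 and a camera adjusted p of 0.0430 (adjusted p = 0.465 with an estimated correlation, 0.0511 without pro-B library 1 and 0.0886 with the code term). Irf4, a transcription factor gene, rose by 2.97 (SE 0.36). Early B-lineage genes moved both ways: 9 of 18 fell, 7 rose and 2 did not pass (10 and 7 adjusted over the list alone). Vpreb2, a surrogate light chain gene, fell by 4.45 on the log2 scale (SE 0.43), and Cd24a rose by 1.58 (SE 0.19). Their median was -1.16 and the camera adjusted p was 0.0138 (adjusted p = 0.858 with an estimated correlation, 0.0657 without pre-B library 1 and 0.0910 without the low-count filter).

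Of 17 glycolysis genes, 11 fell, 0 rose and 6 did not pass (11 fell adjusted over the list alone), with a median of -0.76. Aldoc, which encodes the glycolytic enzyme aldolase C, fell by 1.96 on the log2 scale (SE 0.36, adjusted p = 0.0035). The camera adjusted p was 0.000343 (adjusted p = 0.727 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 10 fell, 0 rose and 67 did not pass (10 fell adjusted over the list alone), with a median of -0.41 and a camera adjusted p of 0.000928 (adjusted p = 0.902 with an estimated correlation, 0.155 with fry and 0.0738 with pro-B library 3 alone). Rps2 fell by 1.06 on the log2 scale (SE 0.18). Among markers of other cell types, the granulocyte and monocyte, natural killer and T-lineage lists were lower by the camera test, but none of them with an estimated correlation (adjusted p = 0.902, 0.759 and 0.759), and most of their members did not pass. The natural killer list also did not pass with the granulocyte list mean as a covariate (0.165), nor the T-lineage list with pro-B library 3 alone (0.0738). The erythroid (adjusted p = 0.191), megakaryocyte (0.849, median 0.37), dendritic (0.620) and stromal (0.656) lists did not pass. The erythroid list passed as lower without pro-B library 2 (0.0401), without pre-B library 2 (0.0471) and with pro-B library 3 alone (0.000647), and the stromal list as higher with the granulocyte list mean as a covariate (0.0229). Of 24 granulocyte and monocyte genes, 4 fell, 0 rose and 20 did not pass (4 fell adjusted over the list alone), with a median of -1.66. Their camera adjusted p was 0.00213 (adjusted p = 0.902 with an estimated correlation, and 0.0886 with the code term). Retnlg fell by 2.47 on the log2 scale (SE 0.55, adjusted p = 0.0114), but did not pass without pre-B library 2 (adjusted p = 0.0954). S100a9 read 657 and 214 CPM in pre-B against 692 to 2609 CPM in pro-B. Of 13 natural killer and innate lymphoid genes, 1 fell (Klrb1c, -5.31, SE 0.59) and 12 did not pass, with a median of -1.68 and a camera adjusted p of 0.00441 (adjusted p = 0.759 with an estimated correlation). Of 19 T-lineage genes, 5 fell, 1 rose (Cd2) and 13 did not pass (9 and 2 adjusted over the list alone), with a median of -2.19. Zap70 (-2.56, SE 0.42) and Lat (-2.35, SE 0.45) fell, and both encode T-cell receptor signalling proteins. The T-lineage list had a camera adjusted p of 0.0176 (adjusted p = 0.759 with an estimated correlation, 0.190 without pre-B library 1 and 0.107 in a fit of these groups alone). The other 17 lists had adjusted p between 0.0794 and 0.849. Of these, the histone list passed as lower with the code term (1.07e-05), without pro-B library 2 (0.0401), without pre-B library 2 (0.000775) and with pro-B library 3 alone (0.000871). The oxidative phosphorylation list did so with the code term (0.0314), relative log expression factors (0.0383) and without pro-B library 3 (0.0230). The cell cycle list did so without pro-B library 2 (0.0447). With pro-B library 3 alone, the cell cycle and interferon-stimulated lists were also called lower, on 1 control library. Among the 17 lists, the germinal centre list had a median of -0.13 and a mean of -0.28 with a test direction of up. The p53 list had a median of 0.10 and a mean of -0.15 with a test direction of up.

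In all, 1898 genes rose and 1409 fell from pro-B to pre-B, of which 927 and 1013 changed at least 2-fold (same test). The unadjusted p was under 0.05 for 5316 genes, and the groups did not overlap in 54.1% of genes, against 20% by chance. Rises numbered 1135 without pro-B library 1 and 1089 without pre-B library 2. Falls numbered 869 without pro-B library 1, 835 without pre-B library 1 and 505 without pre-B library 2. With the code term 1890 genes rose and 1258 fell. Outside code 87 there is 1 library per group, pre-B library 2 and pro-B library 3, of different codes. Calls between them took their spread from the other groups. Of the genes called higher there, 97.7% were also higher within code 87 (1 pre-B and 2 pro-B libraries), against 50.7% of all genes. Of those called lower there, 97.2% were lower within it, against 49.3%. Median differences of these genes were 1.91 outside and 1.36 within the code for rises, and -2.21 and -1.60 for falls. Of 73 named list members that passed, 41 did so whichever library was left out. Requiring changes beyond 2-fold gave 277 rises and 293 falls, and pro-B library 3 alone as control gave 408 and 338.

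The comparison of FOB with pre-B cells spans the step from a dividing marrow precursor to a resting mature cell. It also changes the tissue and the RAG genotype, and no code is shared by the groups. Rag1, which encodes a subunit of the receptor gene recombinase, read 2519 ± 621 CPM in pre-B (SD, n = 2) and had 1 count over the FOB libraries, a pooled ratio of 42178 with a 95% counting interval of 7570 to 1665951. Cr2, the complement receptor CD21, rose from 3.82 ± 0.277 to 757 ± 4.23 CPM (n = 2 each), a log2 change of 7.63 (SE 0.37, adjusted p = 6.32e-07). Fcer2a, which encodes CD23 and with Cr2 defines the sort, rose from 0.997 ± 0.127 to 807 ± 171 CPM, a log2 change of 9.68 (SE 0.59, adjusted p = 1.39e-06). Cell cycle genes fell almost as a whole: 34 of 35 fell and 1 did not pass, among them the spindle gene Tpx2 (198 to 10.1 CPM, log2 -4.28, SE 0.18, adjusted p = 4.50e-07).

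The chemokine receptor gene Ccr6 had no counts in pre-B and was at least 1030.2-fold higher in FOB, with the floor set at 3 counts over the group. Nuggc, likewise without counts in pre-B, was at least 137-fold higher. Egr3 had 1 count in pre-B (pooled ratio 3084, interval 553 to 121872) and Fcrl5 had 2 (ratio 639, interval 176 to 5289). Pxdc1 (log2 8.49), Icosl (7.61), Lta (7.59) and Setbp1 (7.48) completed the 10 largest rises. The largest falls besides Rag1 were in genes without counts in FOB: Flrt2 was at least 1428-fold lower, Me1 at least 1366-fold, Prg2 at least 999.7-fold, Camp at least 770.5-fold, Erg at least 702-fold, Chi3l3 at least 664-fold, Igll1 at least 516-fold and Lcn2 at least 357-fold. S100a8 had 1 count in FOB (ratio 7324, interval 1314 to 289289). Whether reads of Chi3l3 can be told from those of its close paralogs was not tested. Prg2, Camp, Chi3l3, Lcn2 and S100a8 are expressed in granulocytes. Of these 20 genes, Prg2 alone did not pass in an omission, without FOB library 2 (adjusted p = 0.0565). Of the same 20, 7 did not pass with the code term: Ccr6 (adjusted p = 0.0723), Egr3 (1), Nuggc (0.0931), Flrt2 (0.381), Me1 (1), Prg2 (0.0731) and Chi3l3 (0.0596).

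All 60 replication-dependent histone genes fell, with a median of -2.85. Examples were Hist1h1a (-5.04, SE 0.30) and Hist1h2bm (-4.29, SE 0.23). Of 18 cohesin, condensin and Ctcf genes, 12 fell, 0 rose and 6 did not pass (15 fell adjusted over the list alone), with a median of -1.04, and the condensin genes Ncaph (-3.13, SE 0.19) and Ncapg (-3.53, SE 0.26) were among them. The camera adjusted p was 1.38e-53 for cell cycle genes (adjusted p = 0.00388 with an estimated correlation), 1.06e-35 for histones (adjusted p = 0.137) and 1.37e-07 for cohesin and condensin (adjusted p = 0.186). Adjusted over the list alone, 34 cell cycle genes and 60 histone genes fell. Of 77 oxidative phosphorylation genes, 48 fell, 1 rose (Atp5sl, named after its value was seen) and 28 did not pass (56 and 1 adjusted over the list alone), with a median of -0.67 and a camera adjusted p of 5.38e-06 (adjusted p = 0.402 with an estimated correlation). Cox5b (-1.08, SE 0.16) and Ndufc1 (-1.50, SE 0.22) were examples. Of 77 cytosolic ribosomal protein genes, 11 rose, 1 fell (Rpl3l, -4.68, a muscle paralog) and 65 did not pass (2 and 1 adjusted over the list alone), with a median of 0.35. Their camera adjusted p was 0.00343 (adjusted p = 0.822 with an estimated correlation, 0.221 without FOB library 2, 0.678 with the code term and 0.124 with the Rn45s covariate).

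Of 23 mature follicular genes, 21 rose, 0 fell and 2 did not pass (21 rose adjusted over the list alone), with a median of 3.53 and a camera adjusted p of 4.40e-40 (adjusted p = 0.000106 with an estimated correlation). Bcl2, a survival gene, rose by 5.85 (SE 0.23, adjusted p = 4.50e-07) and Ciita by 3.53 (SE 0.18, adjusted p = 7.55e-07). Of 18 early B-lineage genes, 16 fell, 0 rose and 2 did not pass (17 and 1 adjusted over the list alone), with a median of -5.69, or -4.71 with the 3 members at 0 counts set to their bound. Il7r, the interleukin-7 receptor gene, fell by 9.52 on the log2 scale (SE 0.58, adjusted p = 1.39e-06). The camera adjusted p was 3.12e-24 (adjusted p = 0.0244 with an estimated correlation). Of 24 B-lineage identity genes, 8 rose, 3 fell (Syk, and Tcf3 and Spib, which were named after their values were seen) and 13 did not pass, with a median of 0.23 and a camera adjusted p of 0.00402 (adjusted p = 0.402 with an estimated correlation, 0.0543 without pre-B library 1, 0.0721 with the code term and 0.232 with the Rn45s covariate). Ms4a1, which encodes CD20, rose by 7.08 (SE 0.43). Of 15 germinal centre genes, 8 rose, 4 fell (Cxcr4, Neil1, Polh and Plxnb2, the last 3 named after their values were seen) and 3 did not pass (10 and 4 adjusted over the list alone), with a median of 2.26 and a camera adjusted p of 0.00351 (adjusted p = 0.0751 with an estimated correlation). Bcl6, a transcriptional repressor gene, rose by 2.78 (SE 0.30). Of 16 immediate early genes, 7 rose, 0 fell and 9 did not pass (10 rose adjusted over the list alone), with a median of 2.73 and a camera adjusted p of 3.74e-05 (adjusted p = 0.410 with an estimated correlation). This list turned to the other direction with the code term (adjusted p = 0.439). The FOB libraries stood apart: relative to pro-B, the list mean was 0.92 in FOB library 1 and 2.82 in FOB library 2, whose Rn45s shares were 12.5% and 27.4%. With the Rn45s share as a covariate the list still passed (adjusted p = 0.0181). Nr4a1, an orphan nuclear receptor gene, rose by 6.03 (SE 0.75; 29.3 and 146 CPM in the FOB libraries) and Ier2 by 2.56 (SE 0.40).

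The granulocyte, erythroid and stromal lists were lower in FOB by the camera test, but none of them with an estimated correlation (adjusted p = 0.402 for each), and the megakaryocyte list did not pass (0.506). Of 24 granulocyte and monocyte genes, 17 fell, 0 rose and 7 did not pass (20 and 1 adjusted over the list alone), with a median of -7.37, or -6.35 with members at 0 counts set to their bound. S100a9 fell from 436 to 0.420 CPM (log2 -10.26, SE 1.37, adjusted p = 0.000269). Of 14 erythroid genes, 13 fell, 0 rose and 1 did not pass (13 fell adjusted over the list alone), with a median of -5.53, or -5.12 at the bound. Slc4a1, the red-cell anion exchanger gene, fell by 7.47 on the log2 scale (SE 1.26). Of 12 stromal, endothelial and osteoblast genes, 8 fell, 0 rose and 4 did not pass (9 fell adjusted over the list alone), with a median of -5.47, and the collagen gene Col1a2 fell by 6.94 on the log2 scale (SE 1.04). The camera adjusted p was 1.86e-07, 1.65e-05 and 0.00575 for these 3 lists. The other 13 lists had adjusted p between 0.0534 and 0.986. The mitochondrial ribosomal protein list passed as lower without the low-count filter (0.000743), with the code term (0.0219), with fry (0.00730), and without pre-B library 2 (0.00877) or FOB library 2 (0.00570). Among the 13 lists, the plasma cell list had a median of -0.59 and a mean of 0.16 with a test direction of down. It passed as lower with fry (adjusted p = 0.0124). The interferon-stimulated list was called higher without pre-B library 2, a fit with 1 pre-B library. The dendritic cell list had a median of 0.20 and a mean of -0.31 with a test direction of up.

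In total, 1594 genes rose and 2826 fell from pre-B to FOB, of which 1170 and 2002 changed at least 2-fold. The unadjusted p was under 0.05 for 6092 genes, and the groups did not overlap in 69.1% of genes, against 33.3% by chance. Rises numbered 843 without pre-B library 1, 919 without FOB library 1 and 879 without FOB library 2. Falls numbered 1814, 1703 and 1271 in the same order. With the code term, which links these groups only through other groups, 524 genes rose and 1177 fell, and changes beyond 2-fold numbered 520 and 1121. Of 89 named list members that passed, 60 did so whichever library was left out.

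**Figure D3:**
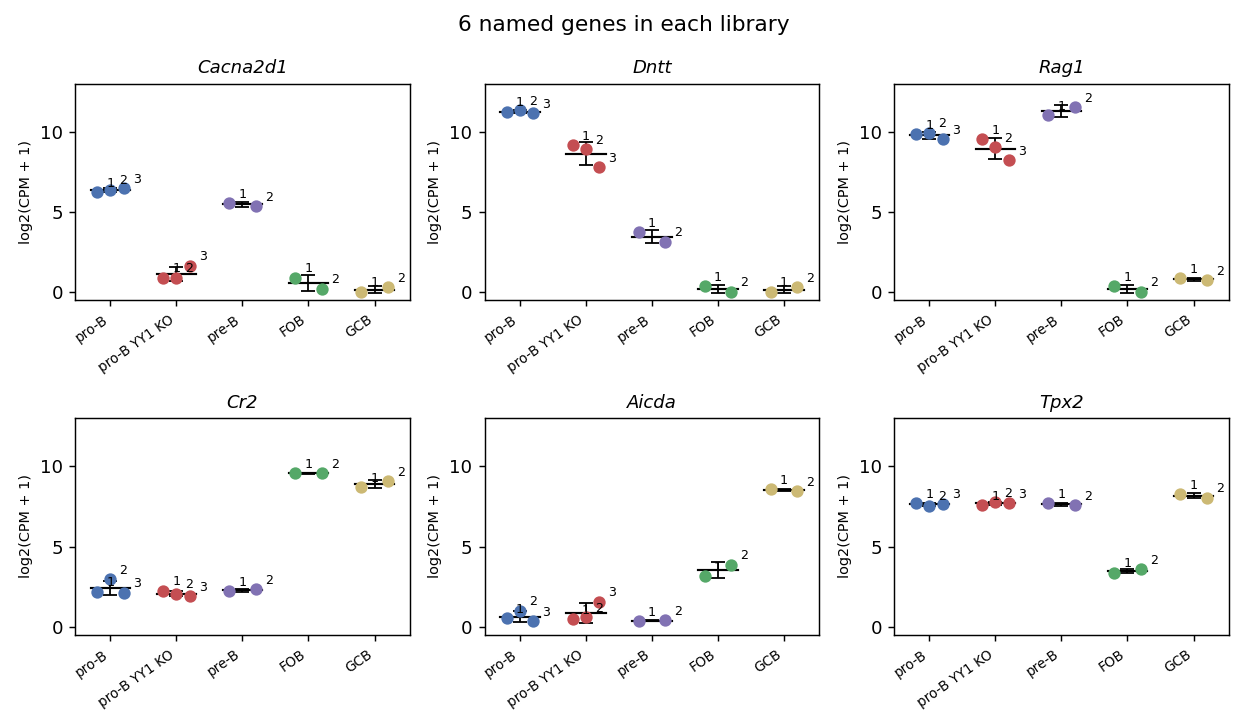
Log2 of CPM plus 1 for 6 named genes in each library, 1 point per library numbered by replicate, with the group mean and SD as bars. Cacna2d1 reads 80.8 CPM on average in pro-B and 1.26 CPM in KO, Dntt 2431 and 423 CPM, and Aicda 10.7 CPM in FOB and 368 CPM in GCB.

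The comparison of GCB with FOB cells contrasts immunized, dividing B cells with resting ones from the same organ. Aicda, the deaminase gene needed for somatic hypermutation and class switching, rose from 10.7 ± 3.99 to 368 ± 20.7 CPM (SD, n = 2 each), a log2 change of 5.05 (SE 0.49, adjusted p = 3.90e-05). Tpx2 rose from 10.1 ± 1.14 to 287 ± 29.6 CPM, a log2 change of 4.81 (SE 0.19, adjusted p = 7.33e-07). Of 35 cell cycle genes, 34 rose and 1 did not pass, and 14 of 15 germinal centre genes rose. The transcription factor gene Sox4 fell from 26.0 ± 1.05 to 0.999 ± 0.750 CPM, a log2 change of -4.79 (SE 0.70, adjusted p = 0.000626). The sort used Fas, which read 101 ± 13 CPM in GCB and 8.51 ± 1.10 CPM in FOB.

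By fitted values, the other largest rises were Klhl23, Slpi (log2 5.34), Igj (5.19), Gcsam (5.15), a germinal centre signalling gene, Fads2 (5.02), Kifc1 (4.94), Atp11a (4.83) and Esco2 (4.78). Klhl23 had no counts in FOB and 6 in GCB, at least 3.38-fold higher, so its rank rests on a fitted value that the counts do not bound. The other largest falls were Xist (log2 -10.23), Irs1, Mei4, Epb4.1l4b, Osm, Pdk2, Scn2b, Atp1b1 (-4.53) and Wls (-4.23). Irs1, Mei4 and Epb4.1l4b had no counts in GCB and were at least 6.14-fold, 5.37-fold and 4.34-fold lower, and the same holds for their rank. Osm had 1 count in GCB (ratio 55.3, interval 9.69 to 2210), Pdk2 had 2 (ratio 44.1, interval 12 to 368) and Scn2b had 1 (ratio 28.0, interval 4.78 to 1129). Xist, the RNA of the inactive X chromosome, read 1183 and 371 CPM in the FOB libraries and 0.782 and 0.437 CPM in the GCB libraries, although the labels give pooled sexes for every group. Ddx3y, from the Y chromosome, read 80.5 and 114 CPM in FOB and 158 and 122 CPM in GCB. The fall of Xist was not separated from a difference in sex between these libraries. Of these 20 genes, 14 passed whichever library was left out. Igj did not pass without FOB library 1 or 2 (adjusted p = 0.204 and 0.176) or GCB library 1 or 2 (0.128 and 0.0794). Klhl23 did not pass without FOB library 2 (0.251) or GCB library 1 or 2 (0.0604 and 0.0709). Epb4.1l4b did not pass without FOB library 1 or 2 (0.0623 and 0.0663) or GCB library 1 or 2 (0.135 and 0.0770). Irs1 did not pass without FOB library 1 (0.0724) or GCB library 1 or 2 (0.161 and 0.0986). Xist did not pass without GCB library 1 or 2 (0.0679 and 0.0572), nor Pdk2 without GCB library 1 (0.0842). Klhl23 did not pass with the code term (0.166), nor did Irs1 with a term for the replicate number (0.0634).

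Cell cycle genes had a median of 3.87 and a camera adjusted p of 3.22e-96 (adjusted p = 0.000555 with an estimated correlation), and 34 rose adjusted over the list alone. Germinal centre genes had a median of 3.58 and a camera adjusted p of 1.15e-26 (adjusted p = 0.000202 with an estimated correlation), with 0 falls, 1 not passing and 14 rises adjusted over the list alone. S1pr2, which confines B cells to germinal centres, rose by 4.75 (SE 0.35), Mybl1 by 4.51 (SE 0.25) and the error-prone polymerase gene Polh by 3.07 (SE 0.22). Of 60 histone genes, 54 rose, 0 fell and 6 did not pass (56 rose adjusted over the list alone), with a median of 2.76 and a camera adjusted p of 8.18e-48 (adjusted p = 0.0824 with an estimated correlation). Hist1h2bm rose by 4.45 (SE 0.23). Of 18 cohesin, condensin and Ctcf genes, 11 rose, 0 fell and 7 did not pass (12 rose adjusted over the list alone), with a median of 1.25, and Ncapg rose by 4.40 (SE 0.27). Their camera adjusted p was 4.48e-12 (adjusted p = 0.0847 with an estimated correlation).

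Of 77 oxidative phosphorylation genes, 47 rose, 1 fell (Atp5sl, named after its value was seen) and 29 did not pass (55 and 1 adjusted over the list alone), with a median of 0.75 and a camera adjusted p of 2.54e-10 (adjusted p = 0.236 with an estimated correlation). Cox6c rose by 1.22 (SE 0.19) and Atp5f1 by 1.08 (SE 0.16). Of 73 mitochondrial ribosomal protein genes, 26 rose, 0 fell and 47 did not pass (36 rose adjusted over the list alone), with a median of 0.56 and a camera adjusted p of 1.17e-05 (adjusted p = 0.551 with an estimated correlation). Mrpl18 rose by 1.65 (SE 0.16). Of 17 glycolysis genes, 6 rose, 1 fell (Slc2a1, a glucose transporter gene named after its value was seen) and 10 did not pass, with a median of 0.88 and a camera adjusted p of 0.00273 (adjusted p = 0.551 with an estimated correlation). Gapdh rose by 2.07 (SE 0.22) and Tpi1 by 2.12 (SE 0.27), both glycolytic enzyme genes.

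Of 23 mature follicular genes, 9 fell, 1 rose (Cd86, a costimulatory ligand gene named after its value was seen) and 13 did not pass (11 and 1 adjusted over the list alone), with a median of -0.66 and a camera adjusted p of 2.81e-07 (adjusted p = 0.0131 with an estimated correlation). Bcl2 fell by 2.96 on the log2 scale (SE 0.20), and Ccr7, a receptor that draws cells to T-cell zones, by 3.99 (SE 0.37). Of 23 interferon-stimulated genes, 14 fell, 0 rose and 9 did not pass (16 fell adjusted over the list alone), with a median of -1.53 and a camera adjusted p of 2.04e-06 (adjusted p = 0.551 with an estimated correlation). Ddx58, the viral RNA sensor gene, fell by 2.75 on the log2 scale (SE 0.25) and Mx1 by 3.35 (SE 0.58). The other 17 lists had adjusted p between 0.148 and 0.975. Immediate early genes passed as lower without FOB library 1 (2.26e-05) or GCB library 1 (0.0163), without the low-count filter (0.0278) and in a fit of the 2 groups alone (0.0409), and cytosolic ribosomal protein genes as higher with the code term (0.0105) and without FOB library 2 (0.00287). In the plasma cell list the median was 0.47 and the mean 0.33 with a test direction of down. For the natural killer list the median was 0.00 and the mean -0.76 with a test direction of up.

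In total, 1836 genes rose and 1619 fell from FOB to GCB, of which 1172 and 1151 changed at least 2-fold. The unadjusted p was under 0.05 for 5121 genes, and the groups did not overlap in 69.1% of genes, against 33.3% by chance. Without FOB library 1, FOB library 2, GCB library 1 and GCB library 2 in turn, rises numbered 976, 1100, 1002 and 1210, and falls 829, 846, 646 and 875. With the code term 1632 genes rose and 1341 fell. Outside the code of FOB library 1 and GCB library 2 there is also 1 library per group, FOB library 2 and GCB library 1, of different codes. Calls between them took their spread from the other groups. Of the genes called higher there, 99.5% were also higher within the shared code (1 library per group), against 40.0% of all genes. Of those called lower there, 98.9% were lower within it, against 49.0%. Median differences of these genes were 2.17 outside and 2.18 within the code for rises, and -1.95 and -1.70 for falls. Of 62 named list members that passed, 48 did so whichever library was left out. A fit of the 2 groups alone gave 2807 rises and 2644 falls, and requiring changes beyond 2-fold gave 559 and 367.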

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

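The settings with pro-B library 3 alone, KO library 3 alone, the Rn45s share as a covariate, the granulocyte list mean as a covariate and a crossed replicate term were chosen only after the data were seen. Over all settings, counts of genes stayed within 1.5 times their reported value in 75 cases and moved further in 47, and counts of lists stayed in 54 and moved in 6. Single lists kept their side of the threshold, and their direction where they passed, in 1393 cases. They lost the call in 80, gained one in 73 and reversed in 3. Named genes were likewise unchanged in 5872 cases, lost the call in 725, gained one in 131 and reversed in 1. A turn of direction where neither fit passed was counted as unchanged. Unless stated, the cause was not tested.

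With each library left out in turn, rises in KO ranged from 187 to 1480 and falls from 485 to 1647. The ranges were 1089 to 1623 and 505 to 1211 for pre-B, 843 to 1198 and 1271 to 2586 for FOB, and 976 to 1210 and 646 to 875 for GCB. Lists past the threshold numbered 8 to 12 for KO, 8 to 12 for pre-B, 13 to 15 for FOB and 9 to 10 for GCB. The log2 change of Yy1 ranged from -2.78 to -1.36 in KO (adjusted p up to 0.111), 0.36 to 0.55 in pre-B, -0.15 to 0.06 in FOB and 0.14 to 0.23 in GCB, and none of the stage changes passed. Fewer libraries give less power by construction, yet rises and falls in KO were most numerous without KO library 3. A lone library was assumed to vary like those of the other groups.

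The code term gave 135 rises and 341 falls in KO, a Yy1 change of -0.90 (adjusted p = 0.184), and 524 rises and 1177 falls in FOB. It reversed the immediate early list in FOB (adjusted p = 0.439). Fitting only the 2 groups compared gave 512 rises in KO, a Yy1 change of -1.83 (adjusted p = 0.0901), and 2807 rises and 2644 falls in GCB. Relative log expression size factors, no low-count filter and removal of special gene classes left all counts of genes within 1.5 times. DESeq2 gave 1391 rises in KO. In the simulation its calls held more false ones than those of edgeR. The test for changes beyond 2-fold is stricter by construction: it gave 20 rises and, rounded, 1.1e+02 falls in KO, 277 and 293 in pre-B, 520 and 1121 in FOB, and 559 and 367 in GCB.

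With the correlation between genes estimated per list, 0, 2, 3 and 3 lists passed for KO, pre-B, FOB and GCB. With the rotation test fry 1 list passed for KO, that of oxidative phosphorylation (lower, adjusted p = 0.0118). For pro-B library 3 alone as control, KO showed 9 rises, 64 falls, a Yy1 change of -1.87 (adjusted p = 0.275) and 16 lists, and pre-B showed 408 rises and 338 falls. For KO library 3 alone, falls numbered 597, Egr1 reversed to -0.75, the dendritic list reversed with an adjusted p of 0.0189 and the immediate early list reversed with an adjusted p of 0.894.

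The replicate numbers were also tried as a block. The largest correlation of deviations between a KO and a pro-B library fell on the same number for KO libraries 2 and 3 but on pro-B library 2 for KO library 1, so the numbers were not taken as pairs. Libraries of the same number correlated at -0.06, 0.12 and 0.26 for KO, 0.118 and 0.137 for pre-B, 0.07 for FOB and -0.104 for GCB. The block gave 1068 rises and 1408 falls in KO, with Yy1 at -2.12 (adjusted p = 0.00905) and 11 lists. It gave 2013 and 1550 in pre-B with 8 lists, 1831 and 3051 in FOB with 13 lists, and 1966 and 1819 in GCB with 9 lists. The erythroid list then passed in KO (adjusted p = 0.0221) and the T-lineage list no longer passed in pre-B (0.0875). Exchanging the numbers of the FOB libraries gave 2062 rises and 1895 falls in GCB.

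The median log2 change over all genes was 0.02, -0.03, -0.13 and -0.08 for KO, pre-B, FOB and GCB. It was -0.36, -0.71, 0 and 0 without the low-count filter and -0.36, -0.81, 0 and 0 with DESeq2, both of which keep genes with few counts. Depth limits what can be detected: 3 counts correspond to 0.0644 CPM over the pro-B libraries and to 0.273 CPM over the GCB libraries, and per library the floor ran from 0.134 CPM in pro-B library 1 to 0.845 CPM in FOB library 1.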

Other observations

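The tests of library codes and residual Yy1 as explanations, of granule genes, of the granulocyte list mean, of thinned depth and of the covariance, and the settings with pro-B library 3 alone and KO library 3 alone, were chosen only after the result was seen. YY1 is related to Polycomb proteins, and the Polycomb list of 24 tested genes did not pass in the 4 comparisons as reported. In pre-B it passed as higher without pre-B library 1 (adjusted p = 0.0369), without pre-B library 2 (0.0277), without the low-count filter (0.00155) and with fry (0.0209). The list had 1 rise and 2 falls in KO (camera adjusted p = 0.545), 6 and 2 in pre-B (0.0794), 6 and 7 in FOB (0.986), and 8 and 7 in GCB (0.975, median 0.04 with a test direction of down). Single members changed strongly along the stages: Cbx7 rose by 1.86 (SE 0.19) in pre-B and by 1.36 (SE 0.21) in FOB and fell by 1.79 on the log2 scale (SE 0.21) in GCB. Ezh2, the histone methyltransferase gene of the complex, fell by 3.02 on the log2 scale (SE 0.31) in FOB. The 7 tested Hox genes did not pass as a list in KO (adjusted p = 0.743), pre-B (0.849), FOB (0.172) or GCB (0.609), but passed as lower in FOB with fry (0.000673). Without the low-count filter the list held 39 Hox genes in place of 7, and passed as lower in KO (0.0441). The median log2 change over all genes was then -0.36 in KO, and pro-B libraries 1 and 2 hold counts in silent genes. This call was not separated from that background. Hoxb4 fell by 4.13 on the log2 scale (SE 0.58) in GCB.

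Among the 16 unfolded protein response genes, Herpud1 fell in KO (-0.84, SE 0.13), rose in pre-B (2.01) and fell in FOB (-2.01), but in KO it did not pass with the code term (adjusted p = 0.112). The list did not pass as reported (adjusted p = 0.303, 0.849, 0.518 and 0.198 for KO, pre-B, FOB and GCB), but passed in GCB as higher without the low-count filter (0.0252) and in KO as lower with pro-B library 3 alone (0.0461). Its median of 0.13 in pre-B had a mean of -0.15. In KO the germinal centre list did not pass (3 rises and 1 fall of 15, adjusted p = 0.180), but it passed as higher without the low-count filter (0.0218), with the code term (0.00583), and with pro-B library 3 (0.0240) or KO library 3 (0.0114) alone. Bcl6 rose by 2.28 (SE 0.25) in KO, but not past the threshold with pro-B library 3 alone as control (adjusted p = 0.0847). The glycolysis list did not pass in KO (0.583) or FOB (0.290), but passed as higher with the code term in both (0.00583 and 0.0319) and with KO library 3 alone in KO (0.00128). The cohesin, condensin and Ctcf list did not pass in KO (0.492) or pre-B (0.782), nor did the 9 dendritic genes (0.840, 0.620, 0.493 and 0.609 in the 4 comparisons). For the 5 sex-linked genes the adjusted p was 0.771, 0.335, 0.172 and 0.808. In GCB their median was 0.38 and their mean -1.76 with a test direction of down. This list mixes Xist with Y-chromosome genes. These can move in opposite directions where sexes differ, so its test cannot show whether the sexes were balanced. Without pre-B library 1 the sex-linked list was called lower in pre-B and higher in FOB, in fits with pre-B library 2 alone. That library read 0 CPM for Ddx3y and Eif2s3y and 0.109 CPM for Kdm5d, all Y-chromosome genes. Pre-B library 1 read 45.99 CPM for Eif2s3y and 36.15 CPM for Kdm5d. Y-chromosome transcripts were thus nearly absent from pre-B library 2, although the labels give pooled sexes for every group. In KO library 2, Ddx3y read 47.65 CPM while Xist was nearly absent. Xist read 154.8, 699 and 532 CPM in pro-B, 52.5, 0.498 and 139.6 CPM in KO, and 557 and 1981 CPM in pre-B.

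Between the pro-B and KO libraries, 882 genes rose and 1187 fell. There are 10 splits of these 6 libraries into 3 and 3, and only 1 of them, the real one, gave as many genes in either direction. The highest count of the other splits was 0. With 10 splits the share cannot fall under 0.05. Each other split mixes the genotypes, so any difference between them widens the spread within its groups. Few calls there were therefore likely in advance, and the splits cannot tell whether chance gave the calls.

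The first pattern weighed was in list means. The immediate early mean was higher in KO libraries 1 and 2, and the oxidative phosphorylation and cytosolic ribosomal protein means were lower in all 3. Most members of these lists did not pass, and no list passed with an estimated correlation (adjusted p from 0.734 to 0.745). A difference between library codes may explain the immediate early rise: with a code term the list median was 0.56, against 1.41 without it, and the adjusted p was 0.890. For the oxidative phosphorylation and cytosolic ribosomal protein lists the larger adjusted p with the code term was 3.02e-07. Residual Yy1 in KO library 3 is a biological candidate explanation for the weaker immediate early change, but the oxidative phosphorylation list still differed by -0.38 there, against -0.49 among the other libraries. In KO libraries 1, 2 and 3, Yy1 (8.42, 19.1 and 51.2 CPM) rose with the granulocyte and monocyte list mean (-0.19, 1.04 and 2.28). Whether the Yy1 left in KO library 3 came from pro-B cells was not tested. Codes and genotype cannot be told apart for these lists, because 1 code holds both genotypes, with 1 library each.

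The second pattern was the higher level of granulocyte and monocyte genes in KO. More cells of the same mixture as in the pro-B libraries would raise early and late granule genes alike. Late minus early genes differed by 2.13 (SE 0.548) in KO library 1 and 3.01 (SE 0.389) in KO library 2. The pro-B libraries gave -0.22, 0.32 and -0.10. Each SE is over genes within 1 library and does not measure the spread between libraries. The value in KO library 2 lies beyond those of pro-B, which argues against more cells of that mixture there. In KO library 1 the list mean was -0.19, so there was no rise to explain. In KO library 3 the difference was 0.46 (SE 0.255), which leaves more cells of that mixture open. A share of other marrow cells that varies by library is a candidate explanation: the list means were 0.59, -1.16 and 0.57 in pro-B and -0.19, 1.04 and 2.28 in KO, with an exact two-sided permutation p of 0.4 (smallest possible 0.1). The labels name no sort or gate for the marrow cells that would remove granulocytes, S100a9 read 692 to 2609 CPM in pro-B and 1646 to 8405 CPM in KO, and 7 of the 24 genes reached 1 CPM in FOB and 9 in GCB.

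The third pattern was counts in silent genes of pro-B libraries 1 and 2. Greater depth was argued against, since both libraries thinned to the depth of pro-B library 3 still detected 593 and 1306 of 1456 receptor genes, against 40. Reads spread evenly over the genome, as from DNA, were not settled. Counts correlated weakly with exon length (Spearman rho 0.36 in pro-B library 2 and 0.25 in pro-B library 1, over 2374 of 2543 silent genes with a length). Against an even spread, counts per kb in pro-B library 2 fell from 7.70 in genes under 1 kb to 1.67 in genes over 4 kb, but the lengths come from another annotation than the unstated one used for counting. No biological explanation was tested.

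A hypothesis was that loss of YY1 moves pro-B cells along the path to pre-B cells. Of the genes called in both comparisons, 252 rose in both, against 119.7 with independent calls, and 318 fell in both, against 119.6. Rises in KO with falls in pre-B numbered 89, against 88.9, and the reverse 172, against 161. Gene lists went both ways. The early B-lineage list was lower in both (adjusted p = 0.00157 in KO and 0.0138 in pre-B). So was the cytosolic ribosomal protein list (1.18e-07 and 0.000928). With an estimated correlation neither list passed in KO (0.734 and 0.745) or pre-B (0.858 and 0.902). In pre-B, 7 of the 18 early genes rose and 9 fell. Dntt read 2431 CPM in pro-B, 222 to 570 CPM in KO and 9.97 CPM in pre-B. Cd93 went both ways, with 727, 261 and 1160 CPM in the same order. The mature follicular list had a test direction of up in both (0.0948, which did not pass, and 2.30e-11). The B-lineage identity list rose in pre-B (1.55e-19) and had a test direction of down in KO, where it did not pass (0.454). Both comparisons share the pro-B libraries, which alone makes changes go together. The covariance of log2 changes over 13986 genes was 0.370, against a mean of 0.120 and a highest value of 0.128 in 20 simulations with shared controls alone, but the correlation was 0.30 against 0.42. Changes in KO and pre-B may therefore go together beyond the shared controls, but the cause cannot be told apart from differences of pro-B libraries that the simulations leave out.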
